A study of Arabidopsis thaliana with 3 samples.

How the data were processed

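Root tips of 7-day-old seedlings of the line Col0/PlaCCI were treated with hydroxyurea for 6, 17 or 22 h and protoplasted, and a 10x Genomics 3′ v3.1 library was made at each time, per the labels' protocols. The treatment protocol gives 10 µM hydroxyurea and the series design 2 µM, and which was used is not given in the sources used here. The files hold raw UMI counts of called barcodes, which the authors made with Cell Ranger against TAIR10, per the submitters' processing notes and the file headers. The headers name Cell Ranger 5.0.1 for the 6 h and 17 h matrices and 6.0.1 for the 22 h matrix, whereas the notes name 5.0.1 alone, and the notes also name Seurat, whose output was not used here. The 6 h and 17 h files list 27628 genes, and 32833 are listed at 22 h. Only the 27628 shared genes were analysed, of which 27420 are nuclear and all matched the reference annotation (TAIR10.1), and 0.455% of the 22 h UMIs fell in genes listed only there.

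Barcodes with fewer than 1000 UMIs (230 at 6 h, 0 at 17 h and 575 at 22 h) or over 10% organelle UMIs (161, 9 and 77) were left out. The plastid share of UMIs was 0.231%, 0.124% and 0.123% and the mitochondrial share 0.263%, 0.141% and 0.245%. Kept barcodes had medians of 7917.5, 8228 and 16608 UMIs. Scrublet's automatic threshold marked 0, 0 and 1 barcodes, so no doublet was removed in the main analysis. All other analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.

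Cells were clustered on 2000 variable genes scaled within each library, 30 principal components, 20 neighbours and the Leiden method at resolution 1. A cluster was named when at least 3 markers of 1 of 11 fixed marker lists were at least 2-fold above the other cells, in at least 5% of its cells, with a list median log2 of at least 0.5. The 11 marker lists were stem cell niche, root cap, non-hair epidermis, hair epidermis, cortex, endodermis, pericycle, phloem, xylem, procambium and green shoot tissue. The 15 gene lists were replication-coupled histones, replication machinery, G2/M genes, G1 regulators, DNA damage response, glutathione synthesis and recycling, glutathione S-transferases, sulfate assimilation, reactive oxygen enzymes, circadian clock, wounding and protoplasting stress, heat shock, cytosolic ribosomal proteins, auxin response and cytokinin response. Of the genes written in these lists, SCL28 (G2/M), PCS1 (glutathione synthesis) and PEP (cortex) were left out, because the reference holds their gene IDs but gives these symbols to other genes.

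Counts were summed per library and scaled to CPM over all nuclear UMIs. Ratios of list members with at least 20 UMIs in the pair used a pseudocount of 0.5 UMI, and the list median was placed among 10000 random lists drawn for each member from its 200 nearest genes in level. Resampled counting intervals came from 1000 Poisson redraws. Single genes were named for each pair by rule, chosen after the data were seen: at least 200 UMIs in the pair, the same direction in at least 80% of the clusters with at least 50 UMIs of the gene in the pair, at least 3 such clusters, and the 10 largest ratios in each direction with a pseudocount of 1 CPM. For the phase classes every cell was thinned to 2000 UMIs, and a cell was S-high or G2/M-high when its UMIs of the histone and replication lists or of the G2/M list reached the 90th percentile with libraries weighted equally. Cells in both classes (3, 33 and 18) were left out of the class sums. The class contrast compared 3 S-high with 3 G2/M-high sums by edgeR's quasi-likelihood F test with library as a block, TMM scaling and Benjamini-Hochberg adjustment at 0.05, so its spread is that between 3 libraries made at different times. The 10 class genes named in each direction had a mean of at least 10 CPM, the same direction in 3 libraries and the largest log2 values.

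The design, the gene lists, the class rule and most alternatives were set before the data were examined. The naming limits for clusters, the cluster used for background, the leaving out of pool-like barcodes (clusters whose variance over mean of 200 variable genes was at most 1.25 in thinned cells, with at least 20 cells) and the leaving out of the top-scoring Scrublet barcodes at an assumed rate of 0.8% per 1000 barcodes (84, 779 and 336 barcodes) were chosen after seeing the data. The alternatives were TMM scaling, other count minimums, all barcodes, cells with at least 5000 UMIs, thinned cells, clusters with at least 20 cells in every library weighted equally, thinning to 1000 or 4000 UMIs, the 80th and 95th percentiles, resolutions 0.5 and 2, scaling over all libraries, DESeq2, no filter, no library block and each library left out. On simulated counts the edgeR test recovered 8.96%, 59.7% and 97.0% of genes changed 1.5-, 2- and 4-fold, with 7 false calls among 16121 genes.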

Results

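Protoplasts, plant cells freed of their walls, were prepared from root tips of Arabidopsis thaliana seedlings and profiled with droplet-based single-cell RNA sequencing at 3 times of hydroxyurea treatment. Hydroxyurea blocks ribonucleotide reductase and so stalls DNA replication, and the seedlings carried PlaCCI, a fluorescent reporter of cell cycle phase. The labels call the 6 h library S-enriched, the 17 h library G2/M-enriched and the 22 h library G1-enriched, so the comparisons ask which genes and cell classes differed between those times. Each time was represented by 1 library, so no difference between times has a replicate check and none was tested. The 6 h matrix held 3631 barcodes and 82.1 M UMIs, the 17 h matrix 9876 barcodes and 120.2 M UMIs, and the 22 h matrix 7129 barcodes and 200.6 M UMIs. Medians of 6660, 8219 and 13914 UMIs per barcode went with these totals. Filters left 3240 barcodes at 6 h, 9867 at 17 h and 6477 at 22 h. Intervals on levels are exact Poisson and intervals on shares exact Clopper-Pearson at 95%, and both cover counting error only.

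The kept cells formed 27 clusters, of which 10 could be named from root cell type markers. Root cap-like cells (SMB, BRN1 and BRN2) made up 9.66% of cells at 6 h (8.66 to 10.7), 20.9% at 17 h (20.099 to 21.7) and 20.06% at 22 h (19.1 to 21.1), with most of them in cluster 2 at 6 h and 17 h and in cluster 3 at 22 h. Procambium-like cells (PHB and SHR) were 3.92%, 8.42% and 4.05%, in cluster 11 at the first pair of times and cluster 16 at 22 h. Endodermis-like cells (SCR and MYB36) were 0.710%, 3.22% and 5.16%, and non-hair epidermis-like cells (GL2, MYB23 and CPC) 1.98%, 4.58% and 4.76%. Stem cell niche-like cells (PLT1, PLT2, BBM and AGL42) were 0.802%, 2.66% and 1.96%, and phloem-like cells (APL, NAC045 and NAC086) 0.494%, 0.507% and 0.865%. Unnamed clusters held 82.4%, 59.7% and 63.2% of cells, and over 90% of the cells came from 1 library in 5 of the 27 clusters, so these shares describe the libraries. The order of the libraries changed with the clustering for root cap-like, procambium-like and non-hair epidermis-like cells: procambium-like cells were highest at 22 h in each of the 3 other clusterings (3.52%, 3.505% and 3.46%), and non-hair epidermis-like cells were 0.247%, 0.0304% and 21.95% at resolution 0.5. In the 6 h library 1643 barcodes (50.7%), and in the 17 h library 954 (9.67%), lay in clusters whose counts varied between barcodes little more than random draws from a single RNA profile. No barcode of the 22 h library did, and such barcodes are called pool-like here. All of them lay in the unnamed clusters 0, 6 and 21 and counted in the totals, so they lowered every named share, most at 6 h.

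Over whole libraries, endodermis and pericycle markers were highest at 17 h. All 11 endodermis markers were higher at 17 h than at 6 h, and 9 of 11 were higher at 17 h than at 22 h, with 58.7 CPM in total at 17 h against 23.3 at 6 h and 26.5 at 22 h. CASP1, which guides Casparian strip formation in the endodermis, stood at 15.7 CPM at 17 h against 1.23 at 6 h. All 3 pericycle markers with enough UMIs were highest at 17 h, with sums of 0.283, 1.79 and 0.161 CPM. Of the xylem markers 7 of 9 were lower at 6 h than at 17 h, but their sum was highest at 6 h (16.1, 11.5 and 8.72 CPM), where AHP6 made up 84.97% of it. Root cap markers summed to 149 and 183 CPM at 6 h and 17 h and to 68.7 CPM at 22 h. The procambium markers summed to 68.4, 47.3 and 47.6 CPM in order of time, the stem cell niche markers to 51.7, 45.5 and 32.8, the non-hair epidermis markers to 258, 199 and 283, and the hair epidermis markers to 19.1, 17.9 and 10.0. Phloem markers summed to 20.5, 15.7 and 20.8 CPM and cortex markers to 2.84, 5.25 and 7.34 CPM. Genes of green shoot tissue stayed at 1.21, 1.22 and 1.31 CPM.

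The 6 h library, labelled S-enriched, had a higher histone level than the 17 h library, and most replication genes were higher as well. The 24 replication-coupled histone genes, which package newly copied DNA, summed to 7031 CPM at 6 h (7012 to 7049), 5666 at 17 h (5652 to 5679) and 5995 at 22 h (5984 to 6005). HTR1, a histone H3 gene, had 842, 592 and 712 CPM, HTR9 535, 388 and 567, and HTA10, a histone H2A gene, 528, 516 and 412, while HTB9 had 428, 444 and 582. Against 17 h, 19 of the 24 histone genes were higher at 6 h, with a median log2 ratio of 0.38 at the percentile of 100 among 10000 matched random lists. Against 22 h, 15 of 24 were higher, with a median of 0.32 at the percentile of 99.5. Of the 32 replication machinery genes, 28 were higher at 6 h than at 17 h, with a median of 0.51 at the percentile of 100, although their sums were nearly equal (1455 CPM at 6 h, 1453 at 17 h and 1745 at 22 h). PCNA1 and PCNA2, the sliding clamp of DNA polymerase, had 89.6 and 94.4 CPM at 6 h against 63.4 and 59.6 at 17 h and 80.4 and 125 at 22 h. TSO2, a ribonucleotide reductase subunit, and TK1A, a thymidine kinase, were not highest at 6 h, with 511, 738 and 712 CPM and 175, 184 and 231 CPM. Against 22 h, 15 of the 32 replication genes were higher at 6 h, and their median of -0.09 became 0.02 with TMM scaling. The histone median against 17 h was 0.01 when every cell was thinned to 2000 UMIs and 0.08 when clusters were weighted equally. That last setting keeps only the 18 of 27 clusters with at least 20 cells in every library, which hold 46.9%, 81.3% and 54.7% of the cells, so the weights and the choice of cells changed together here and below.

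Genes of G2 and mitosis were highest at 17 h, the library labelled G2/M-enriched. The 36 G2/M genes summed to 1092 CPM at 17 h (1086 to 1098), against 443 at 6 h (439 to 448) and 343 at 22 h (341 to 346). Of the 36, 34 were lower at 6 h than at 17 h (median log2 ratio -1.31, percentile 0), and 34 were higher at 17 h than at 22 h (median 1.79, percentile 100). The gene 3xHMG-box2 (HMGB6), whose protein binds mitotic chromosomes, had 57.1, 174 and 14.4 CPM, and KNOLLE, the syntaxin of the forming cell plate, 29.1, 76.2 and 21.3. CYCB1;1, a mitotic cyclin, had 24.05, 55.3 and 16.7 CPM, and CDKB1;1, a mitotic kinase, 25.4, 56.4 and 38.1. Between 6 h and 22 h the same list was higher at 6 h in 26 of 36 genes, with a median of 0.44, but of -0.48 in the 18 clusters weighted equally. The median of 17 h over 22 h was 1.0 in that setting.

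Regulators of G1 showed no common direction at 22 h, the library labelled G1-enriched. Of the 16 G1 regulators, 10 were higher at 22 h than at 17 h (median log2 ratio of 17 h over 22 h -0.38, percentile 20.6), and 7 were higher at 22 h than at 6 h (median of 6 h over 22 h 0.08, percentile 88.9). The D-type cyclins CYCD3;2 and CYCD2;1 had 73.9 and 39.2 CPM at 22 h against 40.04 and 22.6 at 6 h and 35.8 and 18.6 at 17 h, and CYCD3;3 had 17.61, 17.1 and 22.2 in order of time. The transcript of CDT1A, a replication licensing factor whose reporter protein marks G1 in PlaCCI, was highest at 6 h, with 57.0, 42.0 and 34.4 CPM. Transcript levels do not give the level of that protein. Between 6 h and 17 h 13 of the 16 were higher at 6 h (median 0.25, percentile 98.1).

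Genes of the wounding and protoplasting list were higher at 22 h. All 13 genes of the list were higher at 22 h than at both other times, with sums of 778, 1260.4 and 2909.5 CPM at 6, 17 and 22 h. The median log2 ratio was -2.31 for 6 h over 22 h and -1.55 for 17 h over 22 h, below each of the 10000 matched lists in both cases. Over the alternatives these medians ranged from -2.33 to -1.64 and from -1.58 to -1.17, with -1.64 for 6 h over 22 h in the clusters weighted equally and -1.17 for 17 h over 22 h with every cell thinned. WRKY40, a stress-induced transcription factor, had 33.6, 37.8 and 345 CPM, and JAZ1, a repressor of jasmonate signalling, 64.6, 109 and 492. ERF13 had 54.8, 104 and 307 CPM, and ZAT12 375, 680.2 and 718. Between 6 h and 17 h, 9 of the 13 were lower at 6 h (median -0.37, percentile 0.02), with a median of -0.0889 and 7 of 13 lower without pool-like barcodes. Heat shock genes gave no stable direction at 22 h, with a median of -0.03 for 6 h over 22 h (percentile 65.7) and 0.03 for 17 h over 22 h (percentile 82.4), and 6 of 7 were lower at 6 h than at 17 h (median -0.45, percentile 0.11). MBF1C had 75.01, 75.03 and 60.5 CPM, HSFA2 42.6, 58.1 and 33.0, and HSP101 29.0, 42.6 and 20.15. With clusters weighted equally all 7 heat shock genes were higher at 22 h than at 6 h (median of 6 h over 22 h -0.29), and the median of 17 h over 22 h was -0.74.

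Auxin and cytokinin response genes were lower at 22 h. All 9 auxin response genes were higher at 17 h than at 22 h (median log2 ratio 1.66, percentile 99.99) and 8 of 9 were higher at 6 h than at 22 h (median 1.46, percentile 99.97). IAA1 and IAA14, early auxin-induced repressors, had 167 and 53.5 CPM at 6 h, 247 and 39.96 at 17 h, and 60.6 and 9.75 at 22 h. Of the 7 cytokinin response genes, 6 were higher at 6 h (median 0.84, percentile 99.1) and 6 at 17 h (median 0.70, percentile 98.1) than at 22 h. ARR4, a type-A response regulator, had 63.3, 79.2 and 44.7 CPM, and ARR6 20.23, 20.4 and 5.88. Root cap markers were also lower at 22 h, as given above. Between 6 h and 17 h the medians of both lists were near 0 (0.01 and -0.01, percentiles 40.1 and 33.6). With clusters weighted equally the auxin medians were 0.68 for 6 h over 22 h and 1.24 for 17 h over 22 h.

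The series title names glutathione, and the genes of glutathione synthesis and recycling had their highest sum at 22 h. The 18 genes of glutathione synthesis and recycling summed to 959 CPM at 6 h, 1043 at 17 h and 1539 at 22 h (971, 1097 and 1445 with TMM scaling). Much of that difference was GPX6, a peroxidase of the glutathione peroxidase family, with 252, 366 and 747 CPM. GSH1, which makes the first step of glutathione synthesis, had 87.9, 70.6 and 85.6 CPM, DHAR2 98.6, 109.9 and 105, and GPX8 146, 149.99 and 186. Over the list, 11 of 18 genes were higher at 22 h than at 6 h (median log2 ratio of 6 h over 22 h -0.23, percentile 39.6) and 10 of 18 higher than at 17 h (median of 17 h over 22 h -0.29, percentile 27.7), so the list lay among random lists. Its median of 0.04 between 6 h and 17 h had the percentile of 52.8. The glutathione S-transferases, which attach glutathione to other molecules, summed to 5279.6, 6409 and 7004 CPM, but to 5346, 6743 and 6574 with TMM scaling, so the order of 17 h and 22 h depends on the scaling. Of 36 measured members, 22 were higher at 22 h than at 17 h (median of 17 h over 22 h -0.42, percentile 1.06) and 20 higher than at 6 h (median of 6 h over 22 h -0.28, percentile 12.9), with -0.02 between 6 h and 17 h (percentile 18.0). GSTU19 (1509, 1991 and 1744 CPM) and GSTF8 (819.6, 1412 and 1218) were highest at 17 h, whereas GSTF9 was highest at 6 h with 764, 542 and 323. The 22 h over 6 h median of the S-transferases was 0.02 with clusters weighted equally and 0.52 with every cell thinned.

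Sulfate assimilation, which supplies the cysteine of glutathione, was lower at 6 h. Of 11 genes, 10 were lower at 6 h than at 22 h (median log2 ratio -0.76, percentile 1.43) and 7 lower than at 17 h (median -0.40, percentile 0.19). SERAT2;1, a serine acetyltransferase, had 88.1, 178 and 531 CPM, and APS1, an ATP sulfurylase, 83.7, 70.7 and 161. For 17 h over 22 h the median was -0.34 (percentile 22.2), and -0.86 to -0.17 over the alternatives. The medians of 6 h over 17 h and 6 h over 22 h ranged from -0.87 to -0.14 and from -1.61 to -0.35 over the alternatives, lowest with every cell thinned. The reactive oxygen enzymes had medians of 0.22, -0.14 and -0.26 for 6 h over 17 h, 6 h over 22 h and 17 h over 22 h (percentiles 98.0, 43.5 and 22.2), with CSD1, a superoxide dismutase, at 877, 1051 and 558 CPM. In the DNA damage list the medians were 0.21, -0.17 and -0.52 (percentiles 98.5, 60.5 and 5.95), the last from -0.55 to -0.10 over the alternatives. SMR7, a cell cycle inhibitor induced by DNA damage, was highest at 6 h, with 212, 106 and 24.7 CPM, and BRCA1 had 72.2, 27.3 and 59.3. Circadian clock genes had medians of 0.13, -0.07 and -0.42 (percentiles 60.5, 49.4 and 10.1), and GRP7, a clock-controlled RNA-binding protein, had 3105, 4895 and 2585 CPM. Cytosolic ribosomal protein genes had medians of -0.02, 0.04 and -0.02 (percentiles 17.1, 28.6 and 12.1).

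**Figure D1:**
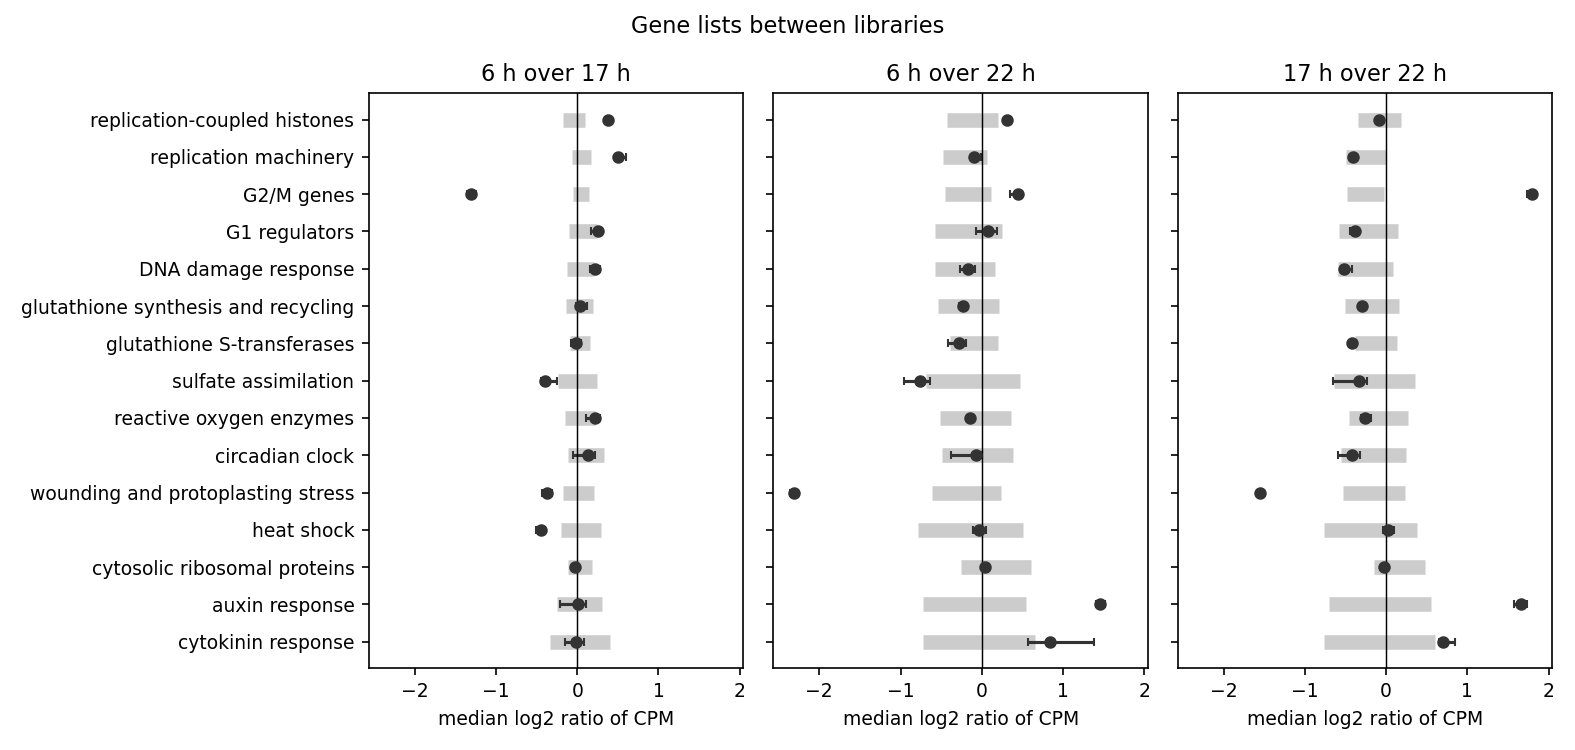
Median log2 ratio of CPM (x axis) of each of the 15 gene lists (y axis) for the 3 pairs of libraries, with points for the observed medians, lines for resampled counting intervals at 95% and grey bars for the central 95% of 10000 matched random lists. The G2/M list sits at -1.31 for 6 h over 17 h and 1.79 for 17 h over 22 h, and the wounding list at -2.31 for 6 h over 22 h.

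All of these ratios are relative to the total of nuclear UMIs. TMM scaling raised the ratios of 6 h over 22 h and 17 h over 22 h by 0.11 and 0.16 (log2), while the medians over all genes were 0.06, -0.14 and -0.20 for 6 h over 17 h, 6 h over 22 h and 17 h over 22 h. Under TMM scaling the direction also flipped for the medians of histones (17 h over 22 h, 0.07), glutathione synthesis and auxin response (6 h over 17 h, -0.02 and -0.05), the clock and heat shock lists (6 h over 22 h, 0.04 and 0.08) and ribosomal proteins (17 h over 22 h, 0.14). By sum, TMM scaling turned the order of 17 h and 22 h for histones, DNA damage genes, S-transferases, ribosomal proteins and the procambium and green shoot markers, that of 6 h and 22 h for ribosomal proteins and phloem markers, and that of 6 h and 17 h for replication genes. Over 8 alternatives 27 of the 45 list medians kept their direction and 18 turned under at least 1. For 6 h over 22 h those of reactive oxygen enzymes and DNA damage (-0.14 and -0.17) reached 0.11 and 0.16, that of G1 regulators (0.08) -0.06 and that of the clock list 0.20. For 6 h over 17 h reactive oxygen enzymes (0.22) reached -0.01, the clock list (0.13) -0.099, S-transferases 0.12, cytokinin response 0.10 and auxin response -0.47. The ribosomal protein medians all turned under at least 1 alternative.

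Single genes with the largest ratios, in the same direction in at least 80% of the clusters with at least 50 UMIs of the gene in the pair, were named by rule. None of the 60 ratios named for the 3 pairs changed direction under an alternative, but 14 moved by more than 1.5 times with every cell thinned and 23 with clusters weighted equally. They were picked as the largest ratios in the same counts, so the kept direction is no separate test. For CASP1, CASP2, DIR14, XTH15 and UCC1, and for PER62 between 6 h and 17 h, only 3 of the 27 clusters had at least 50 UMIs. Between 6 h and 17 h, GSTF2, a glutathione S-transferase (AT4G02520), had 86.4 CPM at 6 h and 3.79 at 17 h, and GSTF6 had 21.2 and 2.67. FSD1, an iron superoxide dismutase, had 51.6 and 3.62 CPM, and ASN1, the asparagine synthetase induced by low sugar, 42.5 and 3.72. The dormancy-associated gene DRMH1 (42.3 and 0.951 CPM), KTI1, PER62, PCR6, AT5G48430 and AT5G40590 completed the genes higher at 6 h. The genes higher at 17 h were CASP1, CASP2, DIR14, XTH15, UCC1, RPP2C, TULP8, iqd8, AT2G47780 and AT3G10880, with 5.22 CPM of CASP2 at 17 h against 0.123 at 6 h.

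Between 6 h and 22 h the named gene with the largest ratio toward 22 h in the unthinned sums was FAMT. FAMT, a methyltransferase gene (AT3G44860), had 1.77, 1.76 and 229 CPM in order of time, and its neighbour AT3G44870 had 7.35, 9.22 and 358. The jasmonate repressors JAZ10 and TIFY10B had 7.28 and 16.7 CPM at 6 h, 6.56 and 34.1 at 17 h, and 157 and 311 at 22 h. MAPKKK21, BCB, AT4G36010, ABR1, TAT3 and GA2OX2 completed the genes higher at 22 h than at 6 h, with BCB at 17.0 and 516 CPM. With every cell thinned the log2 ratio of 6 h over 22 h went from -5.21 to -3.92 for MAPKKK21 and from -4.85 to -6.11 for BCB. That of FAMT went from -6.37 to -5.72, behind BCB, and to -5.32 with clusters weighted equally. AT3G44870, FAMT and MAPKKK21 lead the top genes of cluster 4, and 1146 of its 1152 cells came from the 22 h library. BCB leads those of cluster 3, with 1201 of 1240 cells from 22 h. Library levels of these genes therefore also follow those clusters, although FAMT was lower at 6 h in 17 of 17 clusters with enough UMIs. Against 17 h, FAMT, AT3G44870, ABR1 and JAZ10 were named again. ASN1 had 98.6 CPM at 22 h and 3.72 at 17 h, and DRM1, a dormancy-associated gene, 166 and 5.54. AT3G15450 had 206, 45.9 and 1967 CPM in order of time, and PER62, AT2G32150 and OXS3 were the others of that list.

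The genes lower at 22 h included AGP22 and AGP13, which encode arabinogalactan proteins. AGP22 had 121, 106 and 9.92 CPM, AGP13 47.2, 95.5 and 4.02, GASA1, a gibberellin-regulated gene, 33.9, 87.3 and 4.44, and DPS, a prenyltransferase gene, 106, 105 and 6.81. CASP1, DIR14, HMGB6, AT2G30930, AT2G07689, AT5G14330, AT5G40590 and AT1G07175 were also named for 1 or both pairs. For 6 h over 22 h the log2 ratio of DPS was 3.77, but 2.05 with every cell thinned and 1.62 with clusters weighted equally, and that of AT1G07175 was 3.37 and 2.46 with every cell thinned. AT5G28920, AT1G22800 and AT2G01008 were nearly absent or much lower at 22 h, but each overlaps on the same strand a gene that only the 22 h feature table lists. On the TAIR10.1 assembly AT5G28920 lies on chromosome 5 from 10940035 to 10943378 and had 30.006, 20.6 and 0 CPM (upper limit 0.0186), AT1G22800 on chromosome 1 from 8071789 to 8074357 had 26.5, 27.6 and 0.236, and AT2G01008 on chromosome 2 from 1025 to 3173 had 1458, 787 and 119. Of 12 genes at least 8-fold lower at 22 h, 3 (25%) had such an overlap, against 211 of 17275 genes with at least 200 UMIs (1.22%). Of those 211 overlapping genes, however, only 5 (2.37%) were at least 4-fold lower at 22 h, with no share over all genes at that limit. The partners of the 3 genes had 0.00997 to 0.184 CPM there. Low counts of both genes do not decide the question, because reads left uncounted for both cannot be seen here. Whether the overlap lowered their counts is open. AT1G24880, with 90.8, 45.9 and 0.749 CPM, has near-identical copies in the genome, and its level is uncertain.

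Cells with high scores for DNA replication or mitosis were then counted in cells thinned to 2000 UMIs. Cells with at least 31 UMIs of the histone and replication lists were called S-high, and cells with at least 3 UMIs of the G2/M list G2/M-high. G2/M-high cells were 6.51% at 6 h (179 of 2751, 5.61 to 7.49), 23.2% at 17 h (2080 of 8967, 22.3 to 24.1) and 4.45% at 22 h (268 of 6026, 3.94 to 4.999). The share at 17 h was thus 3.56 times that at 6 h and 5.22 times that at 22 h. S-high cells were 6.25% at 6 h (172 of 2751, 5.38 to 7.22), 12.3% at 17 h (1100 of 8967, 11.6 to 12.96) and 12.99% at 22 h (783 of 6026, 12.2 to 13.9). The lower share at 6 h depends on the limit and the cells: the S-high shares were 17.5%, 18.3% and 26.7% with the 80th percentile as the limit, and 15.6%, 16.5% and 13.999% with clusters weighted equally, where 22 h was lowest. The median of S-list UMIs per thinned cell was highest at 6 h (14, 9 and 10). It was 16 in the pool-like barcodes at 6 h, and 10, 8 and 10 in the other barcodes of the 3 libraries. Without the pool-like barcodes the S-high shares were 13.8%, 13.7% and 12.99%, and the G2/M-high shares 6.27%, 22.9% and 4.45%. Pool-like barcodes were picked for low variance and hardly reach the S limit (0.131% of them at 6 h and 0% at 17 h), so leaving them out raises the S-high share whatever they are. They reach the G2/M limit of 3 UMIs about as often as other barcodes (6.70% at 6 h and 25.9% at 17 h), so a G2/M-high barcode need not be a dividing cell. In the root cap-like cluster 8, which should hold few dividing cells, G2/M-high cells were 0 of 116 (upper limit 3.13%), 5 of 684 (0.731%) and 0 of 22 (upper limit 15.4%), at median depths of 14612.5, 3707.5 and 3552.5 UMIs against 11017, 9269 and 18693 over the thinned cells of each library. Cluster 8 was chosen after seeing the data and sets no general background rate. The shares were 1.95%, 9.21% and 1.75% in the root cap-like cluster 2. In the root cap-like cluster 25 they were 8.33% at 6 h and 5.88% at 17 h. Thinning left out 489, 900 and 451 cells, and at full depth the shares were 5.31%, 11.8% and 12.3% S-high and 3.86%, 18.8% and 3.23% G2/M-high. The classes are ranges of a score, with 0.909%, 1.26% and 3.103% of cells within 1 UMI of the S limit and 16.5%, 17.9% and 7.12% within 1 UMI of the G2/M limit. With the 80th percentile as the limit the 17 h share of G2/M-high cells was 1.74 times that at 6 h, and with the 95th percentile 6.86 times.

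**Figure D2:**
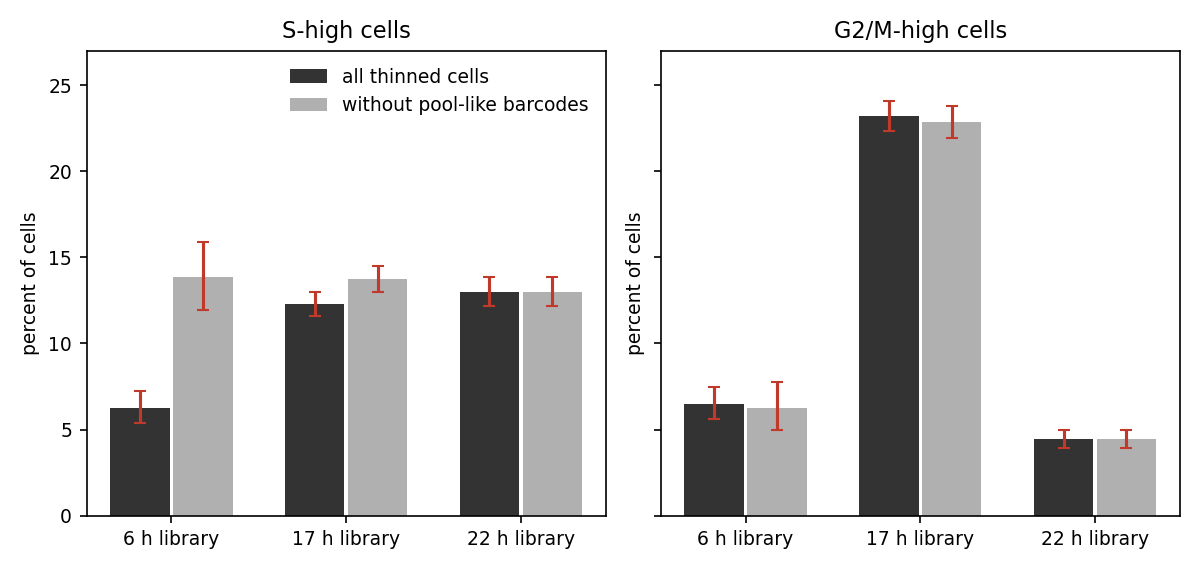
Percent of thinned cells (y axis) that were S-high (left) or G2/M-high (right) in each library (x axis), for all thinned cells (dark bars) and without pool-like barcodes (grey bars), with exact 95% intervals. G2/M-high cells peak at 23.2% at 17 h, and the S-high share at 6 h is 6.25% with and 13.8% without the pool-like barcodes.

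Within libraries, S-high cells were compared gene by gene with G2/M-high cells. The classes are the only contrast with a value in each of 3 libraries, and edgeR's quasi-likelihood test on the 6 class sums, with library as a block and the 92 genes of the class lists left out, called 762 genes higher and 531 lower in S-high cells among 16121 tested. Pool-like barcodes made up 102 of the 176 G2/M-high cells at 6 h and 247 of 2047 at 17 h, against 2 of 169 and 0 of 1067 S-high cells, and without them the test called 680 genes higher and 474 lower. The cluster with the most cells also differed between the classes: the largest share of S-high cells was in cluster 7 at 6 h (18.9%), the root cap-like cluster 2 at 17 h (25.4%) and cluster 10 at 22 h (27.3%), and that of G2/M-high cells in clusters 0, 5 and 5 (50.6%, 35.7% and 60.8%). The class sums used unthinned counts. Median depths were 30407, 7664 and 20015 UMIs in S-high cells and 7510.5, 10500 and 21320 in G2/M-high cells, in order of time. The calls in this and the next paragraphs may therefore follow cell type or depth as well as phase. AT3G53650 and AT2G28720, histone genes outside the fixed list, were higher by 3.23 (SE 0.25, edgeR adjusted p = 0.000124) and 3.37 (SE 0.23, edgeR adjusted p = 5.44e-05) on the log2 scale, each in 3 of 3 libraries. AT3G53650 had 291, 627 and 598 CPM in S-high cells at 6, 17 and 22 h against 40.9, 40.9 and 74.2 in G2/M-high cells. S-high cells were picked by histone and replication transcripts in the same counts. Other histone genes and genes that vary with those lists, here and below, are thus higher partly by the class rule. ABAP1, a regulator of replication licensing, HMGB7, a chromatin protein, and ATBARD1, a partner of BRCA1 in DNA repair, rose by 3.33, 3.08 and 3.05. AT3G14740, CHI1, a flavonoid enzyme, AT5G44020, PER45 and GSTU14 were the other named genes higher in S-high cells, with log2 values from 3.06 to 3.35. GSTU14 is a glutathione S-transferase outside the fixed list. GSTU14, AT5G44020 and PER45 are among the top 10 genes of cluster 14, and CHI1 among those of cluster 23. The 10 genes named as lower in S-high cells were nearly silent there. Cells high for both lists had been left out, and G2/M-high cells were picked by G2/M transcripts in the same counts. Genes that vary with that list therefore differ between the classes partly by the class rule. AT5G16250 had 0.810, 1.71 and 0.996 CPM in S-high cells and 387, 579 and 704 in G2/M-high cells, a log2 difference of -8.95 (SE 0.28, edgeR adjusted p = 3.83e-06). ROPGEF6, which activates ROP GTPases, the kinesin-like gene AT5G55520, AT3G51280, AT5G66230, AT5G56120, AT3G51230, AT5G45700, AT3G52110 and AT3G02640 were the others, with log2 values from -9.08 to -8.46 in 3 of 3 libraries. Without the 22 h library the same test called 2625 genes higher and 2162 lower, without the library block 47 and 205, and with the 95th percentile as the limit 226 and 318.

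Of 30 listed glutathione S-transferases tested, 8 were higher in S-high cells and 0 were lower. The other 22 did not pass at an adjusted p under 0.05 over all genes. Adjusted over the list alone 14 rose and 1, GSTU16 (-1.59), fell. No list was tested as a whole between the classes. GSTU19, the most abundant, rose by 0.68 (SE 0.12, edgeR adjusted p = 0.0129), GSTF8 by 1.21 (SE 0.29, edgeR adjusted p = 0.0427) and GSTU25 by 0.73 (SE 0.13, edgeR adjusted p = 0.0123), each in 3 of 3 libraries. Of the 16 genes of glutathione synthesis and recycling, GPX2 (0.84) and GGT1 (1.01), which breaks down extracellular glutathione, rose and 0 fell, with the same 2 adjusted over the list alone. The count of S-transferases was 3 higher and 2 lower without the 17 h library, 16 higher without the 22 h library, 4 with the 95th percentile as the limit and 0 without the library block.

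Single members of other lists were called between the classes, while most members of each list did not pass. Of 17 DNA damage genes, BARD1 (3.05), WEE1, a kinase that delays mitosis (1.48), and BRCA1 (1.06) rose and 0 fell, while 14 did not pass and the median over the list was -0.37. Adjusted over the list alone 5 rose and 2 fell. The CDK inhibitors KRP3 (1.48) and KRP2 (1.17) rose among 16 G1 regulators, with 4 adjusted over the list alone. Of 8 auxin response genes IAA1, IAA19 and IAA14 rose (0.85, 0.86 and 1.24), and of 5 cytokinin response genes ARR6 and ARR4 (1.0 and 0.74), with the same 3 and 2 adjusted over the list alone. IAA1 is also among the top 10 genes of the root cap-like cluster 2. Of 13 wounding genes ERF13 (0.77) and WRKY53 (1.19) rose, and 10 adjusted over the list alone. RBOHF and RBOHC, NADPH oxidases, rose among 13 reactive oxygen enzymes (1.95 and 2.52), with the same 2 adjusted over the list alone. HSP17.6II (1.43) and HSFA2 (0.69) rose among 6 heat shock genes, with 3 adjusted over the list alone. No gene of the 8 sulfate assimilation, 13 clock or 14 ribosomal protein genes passed in edgeR, over all genes or adjusted over the list alone, with 2, 2 and 9 at an unadjusted p under 0.05 and 0 in each list by DESeq2. Their list medians were 0.31, 0.01 and -0.31, and every ribosomal protein gene was lower in S-high cells in each of the 3 libraries. Without the 22 h library 13 ribosomal protein genes were lower in S-high cells and 11 wounding genes higher.

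**Figure D3:**
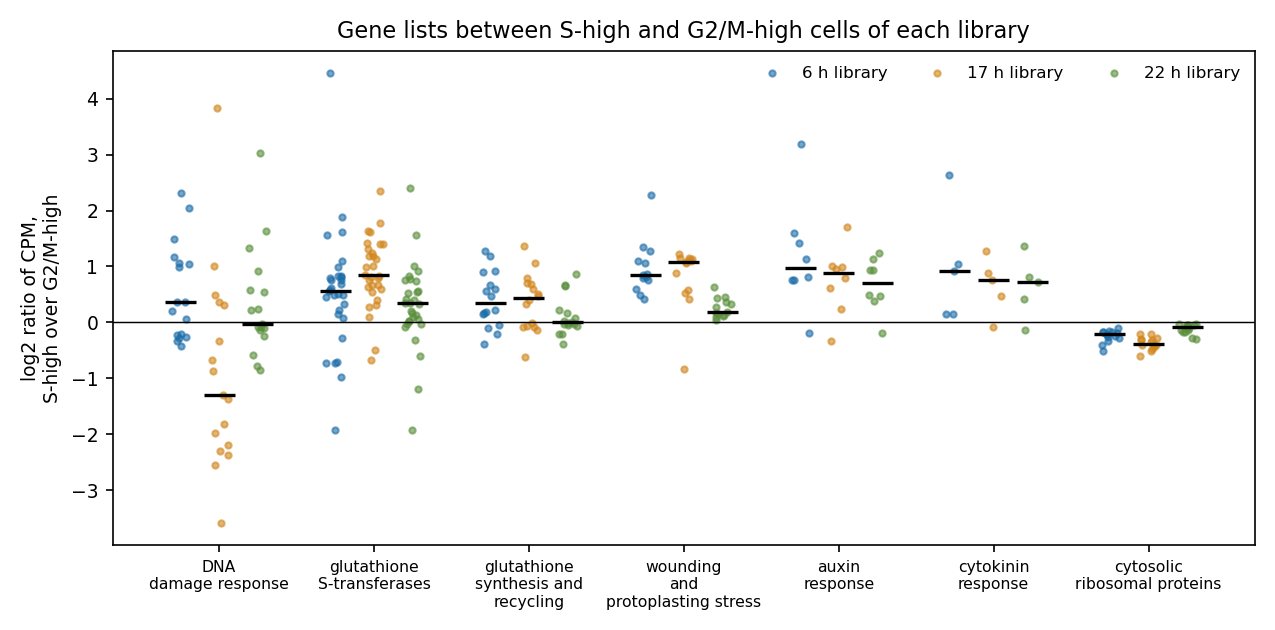
Log2 ratio of CPM in S-high over G2/M-high cells (y axis) for the members of 7 gene lists (x axis), with a point per gene and library (colours) and a line at each library's median. The S-transferase medians are 0.56, 0.84 and 0.34 at 6, 17 and 22 h, and the DNA damage medians 0.36, -1.30 and -0.03.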

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

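All tests in this part were chosen only after the result was seen, except the comparison of glutathione S-transferases within the same clusters. S-high cells, those at or above the 90th percentile limit, were fewer at 6 h, the library labelled S-enriched, than at the other times. This depends on the limit and the cells: with the 80th percentile the shares were 17.5%, 18.3% and 26.7%, with clusters weighted equally 15.6%, 16.5% and 13.999%, and the median of S-list UMIs was highest at 6 h (14, 9 and 10). That median was 10, 8 and 10 without the pool-like barcodes. The share at 6 h was 6.25% (5.38 to 7.22), below the lower limits of 11.6% at 17 h and 12.2% at 22 h. It was itself measured with every cell thinned to 2000 UMIs, so it was lower at equal depth, but thinning is no separate test. At full depth the shares were 5.31%, 11.8% and 12.3%. Thinning also left out 489, 900 and 451 shallow cells, so whether depth plays a part is not settled. Without the pool-like barcodes the S-high share at 6 h was 13.8% and its ratio to the 17 h share 1.01. Those barcodes were picked for low variance and only 0.131% of them at 6 h were S-high, so their removal raises the share in any case and cannot tell whether they account for it. Pool-like barcodes may hold ambient RNA or RNA from many cells, and why they were more frequent at 6 h was not tested. They were unlike in depth, with 6 h medians of 5713 UMIs in cluster 0 (1080 thinned barcodes) and 56561 in cluster 21 (399). Cluster 20, with 284 barcodes at 6 h, shares top genes such as AT2G07671 and AT2G01021 with cluster 0. Too few of those 284 barcodes reached 2000 UMIs for the variance measure, so none was counted as pool-like. Whether time in hydroxyurea altered the share cannot be told from 1 library per time.

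The wounding and protoplasting list was higher at 22 h in 20 of 21 cell clusters compared with 17 h (95.2%) and in 18 of 18 compared with 6 h. A different cell makeup at 22 h is therefore an unlikely sole cause, although the median of 6 h over 22 h went from -2.31 to -1.64 in the 18 clusters weighted equally. Genes listed only in the 22 h table held 0.455% of its UMIs and 0 of the 13 wounding genes overlapped one, so those added genes are not a likely cause either. That check does not cover the other Cell Ranger version at 22 h (6.0.1 against 5.0.1) or changed models of shared genes, which were not tested. Protoplast handling could raise these genes. The heat shock list does not settle this, with a median of 0.0282 for 22 h over 6 h, but with all 7 members higher at 22 h (-0.29 for 6 h over 22 h) when clusters were weighted equally. Handling and the processing of the 22 h library cannot be told apart from time in hydroxyurea without a second preparation processed like the others.

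Of 30 listed glutathione S-transferases, 8 were called higher in S-high cells. The cluster with the most S-high cells differed from that with the most G2/M-high cells in each library. This comparison used means of cells thinned to 2000 UMIs with 10 CPM added, so its values differ from those of the class sums. Within the same clusters the median log2 ratio of the 8 called members went from 1.01 to 0.43 at 17 h (805 S-high and 918 G2/M-high cells in 11 clusters) and from 0.12 to 0.24 at 22 h (326 and 33 cells in 2 clusters). Over all 30 members it went from 0.42 to 0.19 at 17 h and from 0.0312 to 0.25 at 22 h. No cluster at 6 h held enough cells of both classes. A cluster needed at least 10 cells of each class. This left out cluster 5, where 92.3% of thinned cells at 17 h were G2/M-high and 0.126% S-high (84.9% and 0% at 22 h). It also left out the pool-like cluster 6 at 17 h, with 0% S-high. G2/M-high cells fell from 2047 to 918 at 17 h and from 250 to 33 at 22 h. The lower median at 17 h may come from cell type or from the loss of those G2/M-high cells, and the test cannot tell at any time.

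Of the 10 splits of the 6 class sums into 3 and 3, 1, the true classes, called as many genes (1293, with 0 as the highest other count). Only 4 of the 10 part the sums of every library as the classes do, and both numbers are too few for a share under 0.05. The DNA damage list is given here because its S-high over G2/M-high medians pointed in opposite directions between libraries (0.36 at 6 h, -1.30 at 17 h and -0.0314 at 22 h), and the difference was not tested. The 0.4552% of 22 h UMIs in genes absent from the other tables is signal in data that no comparison used.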

How the results depend on the processing

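No paired analysis was possible between times because each time had 1 library. G2/M genes and G2/M-high cells were highest at 17 h under every alternative, and the other values below moved or reversed; the cause was not tested. Equal clusters means the clusters with at least 20 cells in every library (18 of 27 for the list medians), so the cells changed with the weights. For 6 h over 17 h the histone median (0.38) was 0.32 with TMM, 0.44 in cells with at least 5000 UMIs, 0.0088 thinned, 0.0773 with clusters weighted equally and 0.33 without pool-like barcodes. For 6 h over 22 h it (0.32) was 0.42, 0.25, 0.22 and 0.21 with TMM, thinning, equal clusters and no pool-like barcodes. The replication median was 0.45, 0.48, 0.48 and 0.62 for 6 h over 17 h (0.51) with TMM, without Scrublet barcodes, thinned and without pool-like barcodes, and for 6 h over 22 h (-0.09) it reversed to 0.0182, 0.0649, 0.0119 and 0.11 with TMM, thinning, equal clusters and no pool-like barcodes. The G2/M median of 17 h over 6 h (1.31) was 1.36, 1.43 and 1.22 with TMM, equal clusters and no pool-like barcodes, and that of 17 h over 22 h (1.79) 1.95, 1.86 and 1.0 with TMM, thinning and equal clusters. Glutathione synthesis at 22 h over 6 h (0.23) was 0.12, 0.10, 0.18 and 0.16 with TMM, thinning, equal clusters and no pool-like barcodes, and over 17 h (0.29) 0.13, 0.33, 0.24 and 0.32 with TMM, at least 5000 UMIs, thinning and equal clusters. S-transferases at 22 h over 6 h (0.28) were 0.17, 0.15, 0.52, 0.0241 and 0.18 with TMM, no minimum, thinning, equal clusters and no pool-like barcodes, and over 17 h (0.42) 0.25, 0.45 and 0.47 with TMM, at least 5000 UMIs and thinning. The S-high ratio of 6 h over 17 h (0.510) was 0.957, 0.363, 0.946 and 1.01 with the 80th percentile, the 95th, equal clusters and no pool-like barcodes, and that of 6 h over 22 h (0.481) 0.656, 0.620, 1.12 and 1.06, the last pair of each being level or reversed. The G2/M-high ratio of 17 h over 6 h was 2.55 and 4.83 thinned to 1000 and 4000 UMIs, 1.74 and 6.86 with the 80th and 95th percentiles and 2.80 without Scrublet barcodes. That of 17 h over 22 h was 4.42 thinned to 1000 UMIs, 3.29 with the 80th percentile and 2.28 with equal clusters. Genes higher and lower in S-high cells (762 and 531) were 1608 and 1054 with no filter, 47 and 205 with no library block and 226 and 318 with the 95th percentile. Leaving out 1 library each gave 559 to 2625 higher and 437 to 2162 lower. CHI1, AT5G44020, PER45 and GSTU14 lost their call with no library block. The 10 list medians above (of 45) gave 80 values under the alternatives, of which 41 stayed within the counting interval, 35 moved and 4 reversed, and 18 of all 45 medians turned under at least 1. Within their intervals stayed 12 of 28 values of class share ratios, 27 of 54 of cell type shares and 274 of 420 of named library genes, and 193 of 197 values of named class genes kept their call.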
